A study of Arabidopsis thaliana with 8 samples.

How the data were processed

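RNA was measured by sequencing in above-ground tissue of 8 Arabidopsis thaliana genotypes with 3 biological replicate libraries each, 24 in all. Per the labels, 1 µg of RNA extracted with a plant column kit was sequenced on a BGISEQ-500 instrument, STAR 2.5.1b aligned the reads and the genome build was TAIR10. The counting step, the annotation and the strand setting are not given in the sources used here. The deposited raw table holds counts per gene in whole numbers, and the deposited normalized table holds TPM, which the authors made from the counts. The TPM were checked against the counts: for each of 26755 genes the ratio of TPM to count was constant within 0.1% after library scaling, and each library summed to 1000000. The columns are numbered 1 to 24 and were assigned to samples by the numbers in the labels. All results here start from the counts. Library totals ran from 14187145 to 39180748 counts, and chloroplast genes took 0.888 to 2.96% of them.

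Genes were tested with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes low in counts were removed with the edgeR filterByExpr defaults, which left 20346 of 37336 genes, and libraries were scaled with TMM factors. A quasi-likelihood model with 1 term per genotype was fitted to all 24 libraries, and each contrast was tested two-sided with the edgeR quasi-likelihood F test. Each family of p-values over the genes of a contrast was adjusted by the Benjamini-Hochberg method, and a gene with an adjusted p below 0.05 is called. The standard error of a log2 fold change was its size divided by the square root of F. There were 14 contrasts: 7 genotypes against the control summ2-8, the triple combination against each of the 3 doubles, 3 pairwise interactions and the departure of the triple combination from the sum of the 3 single effects. No pairing or blocking was used. The common dispersion was 0.0119, a biological coefficient of variation of 10.9%. Principal components were computed on log2 CPM with a prior count of 2.

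Lists of genes, the contrasts, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of 23 lists with 419 members, 407 members matched by gene identifier and symbol. The 12 left out were PAT1, PATH1 and PATH2, which the annotations give without those symbols and which are reported by identifier, and RH6, RH12, SKI2, SKI3, NOT1, SARD4, NGAL2, NGAL3 and UGT75C1. The list of PAT paralogs therefore had no matched member, and 22 lists were tested. Each list was tested with camera on log2 CPM with a preset correlation of 0.01, and also with an estimated correlation and with fry. The p-values were adjusted by Benjamini-Hochberg over the 154 tests of 22 lists in 7 comparisons with the control, and separately over the 66 tests of the triple combination against the doubles. With the preset correlation 46 of the 154 tests passed, with an estimated correlation 0, and with fry, which tests whether a list's genes move 1 way on balance, 39.

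The named genes follow a fixed rule. They are PAT1, PATH1, PATH2 and SUMM2, and the 10 (triple combination) or 5 (other genotypes) largest changes in each direction among called genes with a mean log2 CPM of at least 1, a symbol, and all 3 mutant libraries beyond all 3 control libraries. They are also up to 4 members of each list by smallest adjusted p among lists with a called member. For the triple combination against a double and for the interactions they are the 3 largest in each direction without the library condition. Not every gene the rule names is printed, and genes whose call held in every setting were preferred. A gene with 0 counts in a group has a fold bound from 3 counts over the group, and a gene with 1 to 3 counts has its ratio with an exact 95% counting interval.

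The alternatives were DESeq2 1.42.0 with its Wald test, RLE size factors, no filter on low counts, fits of only the compared genotypes, removal of chloroplast genes (133) and mitochondrial genes (152), and leaving out each library in turn. Agreement was also recomputed for genes with a mean log2 CPM of at least 3. Removal of per-library trends with exon length and GC content, and leaving out the 2 doubles with path2-1, were added after the data were examined. The edgeR test was tested on counts simulated for all libraries from the mean CPM of the control and the fitted dispersions. In the simulated pat1-1 libraries 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. All else was unchanged, unlike the real comparison with its 4653 calls. The test recovered 55.2% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 11 false calls of 164. For the interaction of pat1-1 with path1-4 it recovered 20.9%, 58.2% and 84.9%, with 8 false calls of 117. With a length trend added to the simulated pat1-1 comparison 616 of 772 calls were false, and 5 of 154 after the trend was removed.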

Results

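The data are RNA sequencing counts from above-ground tissue of Arabidopsis thaliana plants grown for 6 weeks at 21 °C in 8 hours of light and 16 hours of dark. PAT1, PATH1 and PATH2 are the Arabidopsis members of the PAT1 family of mRNA decapping activators, and the study looked for genes that affect the developmental programs these proteins regulate. All 8 genotypes carry summ2-8, a mutation in the immune receptor gene SUMM2, so summ2-8 alone is the control and the other genotypes are named here by their further mutations. The pat1-1, path1-4 and path2-1 mutations were studied as 3 single, 3 double and 1 triple combination, with 3 biological replicate libraries for each of the 8 genotypes and 24 libraries in all. Total counts were 23501136, 26216786 and 26440915 in the control, 19482078, 29169867 and 21276608 in pat1-1, 26581585, 14187145 and 20276355 in path1-4, and 23254754, 31327656 and 20797854 in path2-1. They were 22845883, 26185161 and 29663710 in pat1-1path1-4, 33302393, 25314214 and 20135894 in pat1-1path2-1, 39180748, 23161517 and 34458582 in path1-4path2-1, and 26889756, 28173890 and 28612754 in the triple combination. Replicates correlated at r = 0.981 to 0.994 across genes on the log2 CPM scale, where genes are not independent replicates. The tables hold 37336 genes, of which 28486 had a count above 0 and 20346 were tested. Unless another quantity is named, a gene's value is its log2 fold change from the control ± SE, and levels are CPM (counts per 1000000) as mean ± SD, each with n = 3 libraries per genotype. Rose, fell and called refer to an edgeR Benjamini-Hochberg adjusted p below 0.05. These p-values cover the spread between libraries, and the counting intervals given for genes with 1 to 3 counts cover counting error only. The plants stood in pots of 1 of 2 sizes, and the labels give neither the size for each genotype nor whether a library is a pool or a single plant.

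The transcripts of the mutated loci were reduced only in part or not at all. PAT1 (AT1G79090, TAIR10.1 chromosome 1, 29749101 to 29753330) was at 75.3% of the control in pat1-1, 63.5% in pat1-1path1-4 and 77.7% in the triple combination. Its CPM was 47.8 ± 1.99 in the control and 36.0 ± 0.619 in pat1-1, with edgeR Benjamini-Hochberg adjusted p = 0.00538, 5.88e-05 and 0.00446 in those 3 genotypes. In pat1-1path2-1 PAT1 was at 90.3% and was not called (edgeR adjusted p = 0.258). PATH1 (AT3G22270, chromosome 3, 7874145 to 7878812) was at 78.6% of the control in pat1-1path1-4 (edgeR adjusted p = 0.000630) and at 131% in pat1-1path2-1 (edgeR adjusted p = 0.000149). It was at 78.0% in path1-4 (edgeR adjusted p = 0.0250), 93.6% in path1-4path2-1 (0.344) and 86.3% in the triple combination (0.0129). With trends of exon length and GC content removed, a setting added after the data were examined, PATH1 was called in path1-4path2-1 (-0.18, edgeR adjusted p = 0.0294). The path1-4 call ended with only the compared genotypes (0.628), without control replicate 1 (0.0511) or 2 (0.101) and without path1-4 replicate 1 (0.0678) or 2 (0.196), and the triple call without control replicate 1 (0.0565) or triple replicate 2 (0.0691). PATH2 (AT4G14990, chromosome 4, 8565622 to 8569871) was at 105% of the control in path2-1 (edgeR adjusted p = 0.785) and was called lower in no genotype. In the triple combination it was at 118% (edgeR adjusted p = 0.0465), a call that ended with no filter (0.0548), without the 2 doubles with path2-1 (0.0726), without control replicate 2 (0.0918) or 3 (0.187) and without triple replicate 1 (0.158) or 3 (0.0768). SUMM2 (AT1G12280, chromosome 1, 4174875 to 4178021) was called in no genotype, with -0.43 in the triple combination (edgeR adjusted p = 0.0509, and 0.0148 without triple replicate 1). The annotation gives all 4 loci as protein-coding genes, and the counts are per gene, so they do not show which part of a transcript remained.

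Genotypes differed widely in how many genes departed from the control. On the first principal component, with 34.7% of the variance, the 12 libraries with pat1-1 lay above 0 and the 12 without it below 0. The second component held 14.5% of the variance. The 6 libraries of pat1-1path2-1 and path1-4path2-1 lay from -42.2 to -25.5 on the second component and the other 18 from 2.83 to 26.1. The plot of called genes shows 4653 genes in pat1-1, 36 in path1-4, 4 in path2-1, 6356 in pat1-1path1-4, 6631 in pat1-1path2-1, 3958 in path1-4path2-1 and 9230 in the triple combination.

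**Figure D1:**
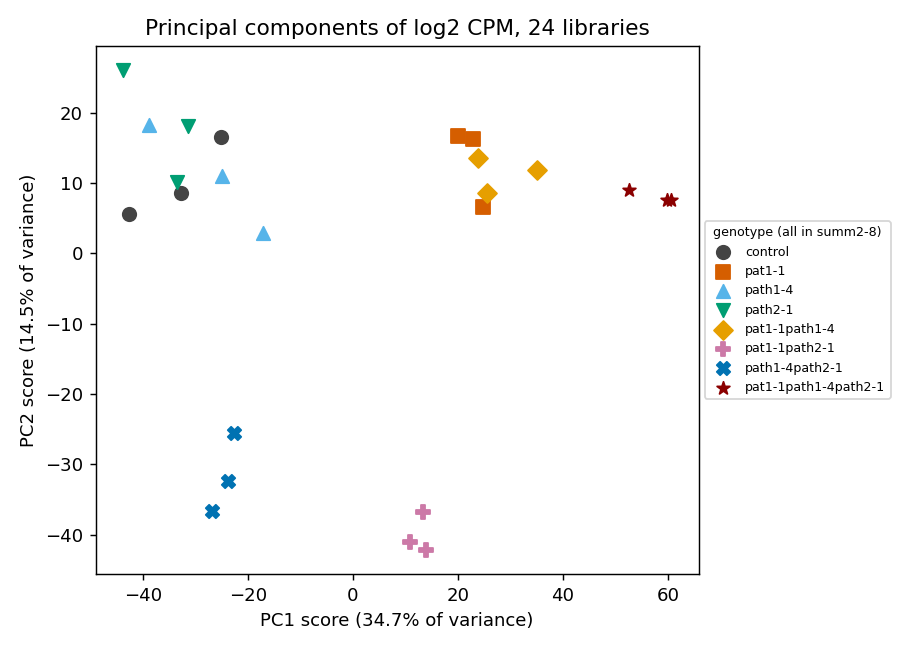
First and second principal components of log2 CPM for the 24 libraries, one marker per library, colored and shaped by genotype. The 6 libraries of pat1-1path2-1 and path1-4path2-1 lie from -42.2 to -25.5 on the second component, apart from the other 18.

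**Figure D2:**
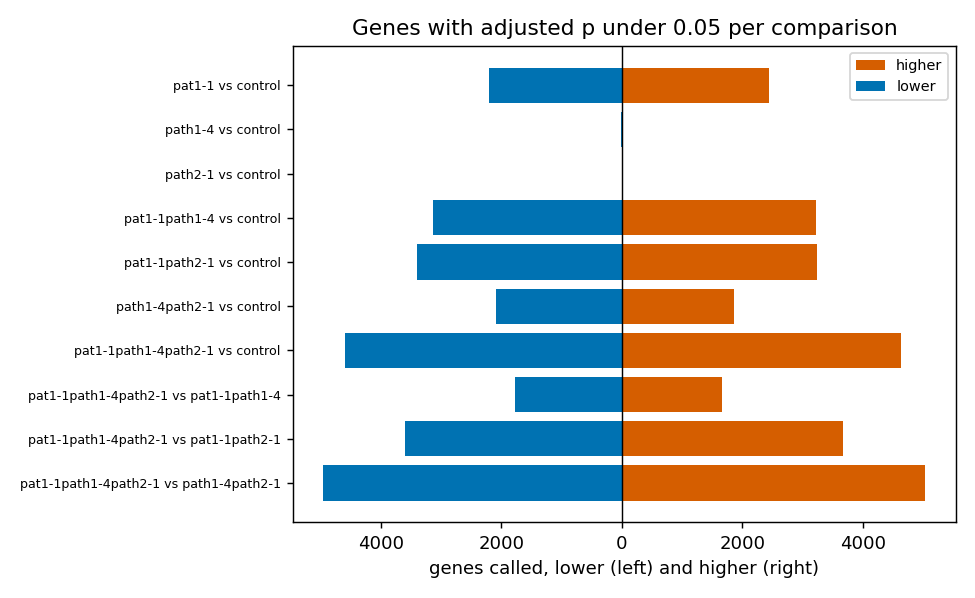
Number of genes called higher (bars to the right) or lower (bars to the left) in each genotype against the control summ2-8 and in the triple combination against each double, by edgeR with Benjamini-Hochberg adjusted p below 0.05 and n = 3 libraries per genotype. Against the control, the triple combination has 4637 higher and 4593 lower, and path2-1 has 2 of each.

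The triple combination asks what happens when all 3 genes are mutated. Of the lists fixed beforehand, most shade and drought genes fell and most heat genes rose. HFR1, a transcription factor gene of shade responses, fell from 67.2 ± 10.6 to 13.0 ± 0.959 CPM. LHY, a morning gene of the circadian clock, rose from 44.8 ± 3.02 to 205 ± 13.1 CPM, and FLC, a repressor of flowering, from 2.22 ± 0.819 to 17.1 ± 1.80 CPM. ASL9, a gene of the LOB domain family, rose from 1.15 ± 0.316 to 6.72 ± 0.840 CPM. In all, 4637 genes were higher and 4593 lower, 2069 of them by more than 2-fold in either direction. Among the largest increases, each with all 3 triple libraries above all 3 control libraries, were the glycine-rich protein gene GRP9 (5.11 ± 0.57, edgeR adjusted p = 4.61e-07), the germin-like GLP9 (3.74 ± 0.43), the glyoxalase gene GLYI4 (3.59 ± 0.53), the calmodulin-like CML41 (3.3 ± 0.43), AT1G65970, also called TPX2 (3.39 ± 1.01), and the metallothionein MT1C (3.22 ± 0.44). The peroxidase PA2 (3.21 ± 0.52), the immune-induced AIG1 (3.16 ± 0.72), the osmotin OSM34 (3.13 ± 0.71) and the glutamate decarboxylase GAD (2.97 ± 0.34) completed the 10 largest among genes that meet the naming rule. Here and below, largest changes are ranked among genes that meet this rule, which leaves out genes without a symbol. The largest decreases included the Nudix hydrolase NUDT24, 157-fold lower (95% counting interval 53.3 to 764, 3 counts against 418), the phosphotransfer gene AHP4 (-6.44 ± 0.95), the laccase LAC2 (-5.12 ± 0.30, edgeR adjusted p = 8.95e-11), the protein kinase CIPK25 (-4.82 ± 0.48) and DAA1 (-4.44 ± 0.60). The ribonuclease RNS1 (-4.39 ± 0.89), the terpene synthase TPS03 (-4.25 ± 0.60), the linker histone HIS1-3 (-4.12 ± 0.30) and MDP40 (-3.78 ± 0.36) were also among them. RNS1 was near the counting floor in the triple combination, so the size of its fold is uncertain. LTP4, a lipid transfer protein gene, was at -4.72 ± 1.36 (edgeR adjusted p = 0.00753, and 0.066 without control replicate 2).

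Most genes of the shade list, the auxin list and the brassinosteroid and gibberellin list fell in the triple combination, and these lists passed camera only at the preset correlation. The shade list shares IAA19, IAA29 and YUC8 with the auxin list and XTH15 and XTH33 with the cell wall list, so these results are not separate. Of the 14 members of the shade and phytochrome-interacting factor list, 12 fell and 2 rose, and 14 passed when adjusted over the list alone. HFR1 was at -2.37 ± 0.15 and HB-2 at -1.85, and camera gave the list an adjusted p = 2.16e-05 (adjusted p = 0.443 with an estimated correlation). Of the 30 auxin genes 17 fell, 2 rose and 11 were not called (20 adjusted over the list alone), among them IAA29 (-2.19 ± 0.13), the auxin synthesis gene YUC9 (-2.58) and the efflux carrier PIN7 (-1.14). The SAUR members among them have near-identical paralogs, so their single values are uncertain. The auxin list had a camera adjusted p = 0.000333 (adjusted p = 0.550 with an estimated correlation). Of the 16 brassinosteroid and gibberellin genes 10 fell, 0 rose and 6 were not called (10 adjusted over the list alone), with a camera adjusted p = 0.00129 (adjusted p = 0.443 with an estimated correlation). The gibberellin synthesis gene GA20OX3 was 23.3-fold lower (95% counting interval 7.60 to 116), and the brassinosteroid synthesis gene BR6OX2 was at -1.55. Of the 19 cell wall loosening genes 7 fell, 4 rose and 8 were not called (12 adjusted over the list alone), with XTH15 at -1.97 and XTH8 at -1.04. That list did not pass camera (adjusted p = 0.25).

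Most drought, cold and photosynthesis genes and 9 of 18 flavonoid genes fell in the triple combination. Of the 17 abscisic acid and drought genes 13 fell, 1 rose and 3 were not called (16 adjusted over the list alone), with a camera adjusted p = 0.000333 (adjusted p = 0.626 with an estimated correlation). NCED3, which encodes an enzyme of abscisic acid synthesis, was at -1.40 ± 0.15, the phosphatase HAI2 at -2.42 and LTI65 at -2.80. Of the 12 cold genes 8 fell, 2 rose and 2 were not called (10 adjusted over the list alone), with a camera adjusted p = 0.00483 (adjusted p = 0.662 with an estimated correlation). COR15B was at -2.35 ± 0.17, and CBF2 and DREB1A, from a tandem gene family whose reads are hard to assign, were at -2.68 and -1.97. Of the 18 flavonoid and anthocyanin genes 9 fell, 2 rose and 7 were not called (13 adjusted over the list alone), with a camera adjusted p = 0.0147 (adjusted p = 0.550 with an estimated correlation). Chalcone synthase TT4 was at -3.04, the regulator PAP1 at -2.91, and the regulator TT8 was 34.9-fold lower (95% counting interval 9.26 to 295). Of the 33 photosynthesis genes 20 fell, 3 rose and 10 were not called (25 adjusted over the list alone), with a camera adjusted p = 0.000333 (adjusted p = 0.737 with an estimated correlation). The antenna genes LHCA2 (-0.76) and LHCB3 (-0.81) fell. CAB1 (-0.94) fell too, and it has near-identical paralogs.

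Most heat and clock genes and 12 of 25 immunity genes rose in the triple combination. Of the 25 salicylic acid and immunity genes 12 rose, 0 fell and 13 were not called (13 adjusted over the list alone), with a camera adjusted p = 0.00566 (adjusted p = 0.793 with an estimated correlation). The regulators NPR1 (0.54 ± 0.08), CBP60G (1.48 ± 0.26) and EDS1 (0.91 ± 0.20) rose. Of the 7 heat and protein folding genes 6 rose, 0 fell and 1 was not called (6 adjusted over the list alone), with a camera adjusted p = 0.00264 (adjusted p = 0.550 with an estimated correlation). HSP70 was at 2.12 and HSP101 at 0.98. Of the 18 clock genes 10 rose, 3 fell and 5 were not called (15 adjusted over the list alone), with a camera adjusted p = 0.0381 (adjusted p = 0.550 with an estimated correlation). LHY was at 2.19 ± 0.11 (edgeR adjusted p = 1.18e-11), RVE1 at 2.09, RVE8 at 1.06 and CCA1 at 0.98.

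Other lists held called members in both directions or did not pass camera in the triple combination. Of the 22 flowering time genes 7 rose, 8 fell and 7 were not called (16 adjusted over the list alone). FLC was at 2.93 ± 0.32 (edgeR adjusted p = 2.90e-07), while AGL20, also known as SOC1 and a promoter of flowering, was at -1.13 and AGL42 at -2.68. Of the 14 cytokinin genes 6 rose, 3 fell and 5 were not called (11 adjusted over the list alone), with ASL9 at 2.54 ± 0.26 (edgeR adjusted p = 1.50e-07), the response regulator RR16 at -1.19 and the cytokinin oxidase CKX5 at -1.24. Of the 22 leaf margin, boundary and meristem genes 7 rose, 4 fell and 11 were not called (11 adjusted over the list alone), with NGA3 at 1.63, the leaf polarity gene AS1 at 0.78 and TCP2 at -0.73. Of the 21 mRNA decapping and decay genes 8 rose, 5 fell and 8 were not called (14 adjusted over the list alone). Of these the LSM ring genes LSM1B (1.14 ± 0.09), LSM3A (1.31 ± 0.12) and LSM2 (0.73 ± 0.10) and the exonuclease gene AT1G77680, known as SOV (1.24 ± 0.08), rose. Of the 26 jasmonate genes 10 fell, 1 rose and 15 were not called (11 adjusted over the list alone), with the synthesis genes LOX2 at -1.75 and AOS at -1.01 and the regulator ORA59 at -2.07. Of the 18 rapid stress and touch genes 5 rose, 6 fell and 7 were not called (11 adjusted over the list alone), with WRKY18 at 1.13 and the deadenylase gene CAF1a at -1.16. Of the 18 glucosinolate genes 7 fell, 1 rose and 10 were not called (8 adjusted over the list alone), with MYB51 at -1.13. The 10 senescence genes split into 3 that rose, 3 that fell and 4 not called (6 adjusted over the list alone), with SEN1 at 0.63 and NAC6, also called ORE1, at -1.67. Of the 10 phosphate and iron genes 2 rose, 3 fell and 5 were not called (6 adjusted over the list alone), with the ferritin FER1 at -1.34. Of the 3 root markers 2 rose and 1 was not called (2 adjusted over the list alone), with the glucosidase PYK10 at 1.76 and NAI2 losing its call without control replicate 1 (0.0542). Of the 2 floral organ markers tested of 6 fixed, the stamen and carpel gene AG fell (-2.04) and the petal and stamen gene PI rose (2.66). Both passed when adjusted over the list alone, but PI had only 6 counts over the control libraries, so its fold is uncertain. The camera adjusted p was 0.730 for flowering time, 0.568 for cytokinin, 0.758 for leaf margin, 0.186 for decapping, 0.124 for jasmonate, 0.785 for rapid stress, 0.0727 for glucosinolates, 0.907 for senescence and for floral organs, 0.299 for phosphate and iron, and 0.160 for root markers. Camera ranked flowering time, senescence and floral organs downward although their medians were 0.00, 0.33 and 0.31, and the mean of flowering time was -0.04.

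**Figure D3:**
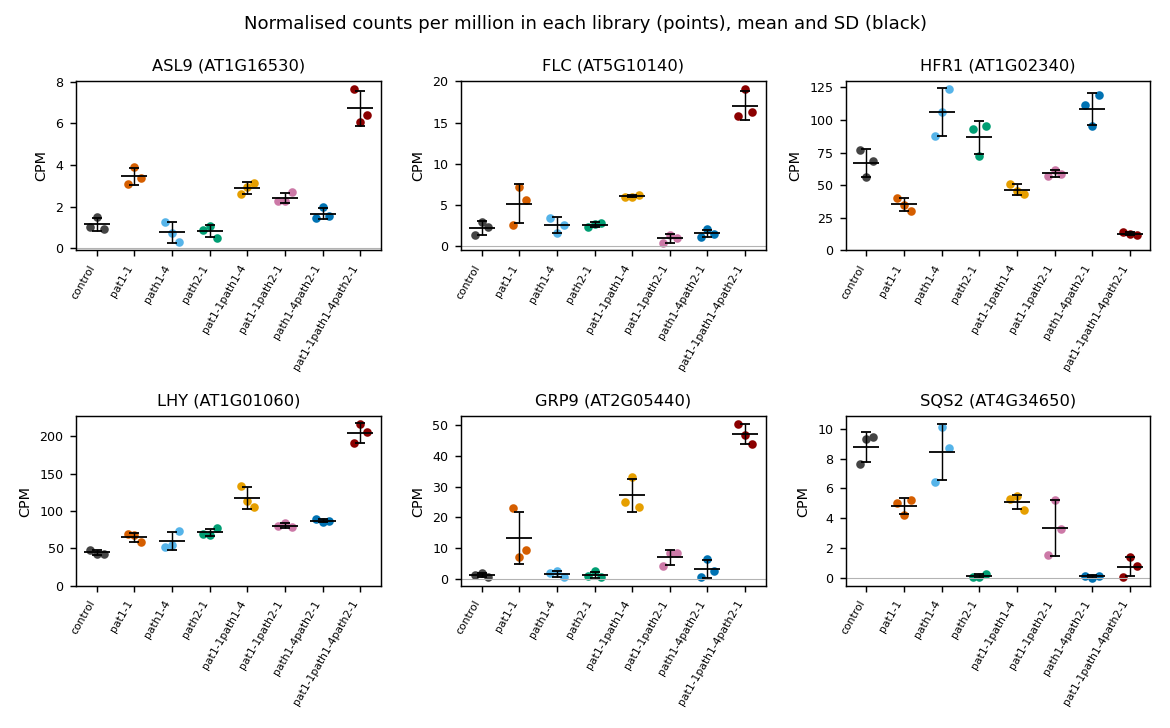
CPM of ASL9, FLC, HFR1, LHY, GRP9 and SQS2 in each library of the 8 genotypes, with points for libraries and bars for the mean and SD (n = 3) on linear axes. HFR1 is at 13.0 ± 0.959 CPM in the triple combination and at 67.2 ± 10.6 in the control.

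The pat1-1 comparison asks what mutation of PAT1 alone changed. Most drought and shade genes fell, while most immunity genes were not called. The polygalacturonase gene PGAZAT was 387-fold higher (95% counting interval 107 to 3201, 706 counts against 2), and NUDT24 was 127-fold lower (95% counting interval 43.2 to 619, 3 counts against 418). The protease inhibitor gene KTI1 was at 69.2 ± 35.5 CPM against 4.33 ± 3.34 in the control, and AHP4 at 1.05 ± 1.01 against 14.8 ± 4.46. ASL9 was at 3.47 ± 0.411 CPM against 1.15 ± 0.316. In all, 2443 genes were higher and 2210 lower, 796 of them by more than 2-fold. KTI1 (4.01 ± 0.84, edgeR adjusted p = 0.00207), AHP4 (-3.84 ± 0.74, edgeR adjusted p = 0.00109), DAA1 (-2.69 ± 0.51), QQS (-2.29 ± 0.40), the sugar transporter SWEET13 (-1.89 ± 0.34) and ASL9 (1.59 ± 0.27) were among the called genes. Of the 25 immunity genes 8 rose, 0 fell and 17 were not called (13 adjusted over the list alone, and 5 of the 8 stayed called with only the compared genotypes), with NPR1 at 0.49 ± 0.08 and a camera adjusted p = 4.50e-06 (adjusted p = 0.671 with an estimated correlation). Of the 10 senescence genes 4 rose, 0 fell and 6 were not called (8 adjusted over the list alone), with SAG13 at 2.11 ± 0.37 and SAG21 at 1.12 ± 0.23 and a camera adjusted p = 0.105. Of these 4, 2 stayed called without pat1-1 replicate 3. Of the 17 abscisic acid and drought genes 9 fell, 0 rose and 8 were not called (10 adjusted over the list alone), with NCED3 at -1.04 ± 0.15 and HAI2 at -1.83 ± 0.31 and a camera adjusted p = 0.000261 (adjusted p = 0.626 with an estimated correlation). Of the 12 cold genes 6 fell, 1 rose and 5 were not called (8 adjusted over the list alone), with COR15B at -1.15 and a camera adjusted p = 0.00841 (adjusted p = 0.696 with an estimated correlation). Of the 18 flavonoid genes 8 fell, 1 rose and 9 were not called (14 adjusted over the list alone), with TT4 at -1.59 ± 0.21 and LDOX at -2.19 ± 0.54 and a camera adjusted p = 0.00298 (adjusted p = 0.550 with an estimated correlation). Of the 14 shade genes 8 fell, 0 rose and 6 were not called (9 adjusted over the list alone), with HFR1 at -0.93 ± 0.14 and a camera adjusted p = 0.00298 (adjusted p = 0.550 with an estimated correlation). The 2 floral organ markers rose (2 adjusted over the list alone), AG by 1.17 ± 0.26 and PI with a call that ended without control replicate 2 (0.0537) or pat1-1 replicate 2 (0.0809). PI had only 6 counts over the control libraries. This list of 2 tested genes had a camera adjusted p = 0.0455 (adjusted p = 0.550 with an estimated correlation). Of the 7 heat genes 2 rose and 5 were not called (2 adjusted over the list alone), with a camera adjusted p = 0.0455 (adjusted p = 0.696 with an estimated correlation). The 2 that rose, HSP17.4 and HSP70, lost their calls without control replicate 2 (0.0637, 0.105) or 3 (0.0527, 0.0933) and without pat1-1 replicate 3 (0.104, 0.0508), and HSP70 also without pat1-1 replicate 1 (0.0779). Of the 18 glucosinolate genes 4 fell, with MYB28 at -0.85, and 14 were not called (5 adjusted over the list alone, camera adjusted p = 0.00483, adjusted p = 0.720 with an estimated correlation). Of these 4, MYB29 and SUR1 lost their calls without control replicate 2 (0.0569, 0.0508) or pat1-1 replicate 2 (0.0525, 0.0765), and SUR1 also without pat1-1 replicate 1 (0.0727) and with only the compared genotypes (0.0592). Of the 18 rapid stress genes 5 rose, with BAP1 at 1.31, and 13 were not called (6 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.768 with an estimated correlation). Of these 5, 3 stayed called without control replicate 2 or 3 and 2 with only the compared genotypes. The decapping list had 6 members that rose, 3 that fell and 12 not called (10 adjusted over the list alone), with LSM1B at 0.68 ± 0.10 and LSM3A at 0.70 ± 0.12 and a camera adjusted p = 0.0952. The number of called genes was 3089 when only the 6 compared libraries were fitted and 2700 without control replicate 2.

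The path1-4 and path2-1 comparisons ask what mutation of PATH1 or PATH2 alone changed, and few genes were called. In path1-4, SHL1 was at 37.3 ± 3.00 CPM against 20.7 ± 1.16 in the control (0.85 ± 0.09, edgeR adjusted p = 1.10e-05), and the cytochrome P450 gene CYP71A25 was at 3.52 ± 0.435 against 9.71 ± 0.679 (-1.47 ± 0.14, edgeR adjusted p = 4.28e-06). In path2-1, the squalene synthase gene SQS2 was at 0.115 ± 0.136 CPM against 8.79 ± 0.995 (-6.35 ± 0.63, edgeR adjusted p = 4.13e-05). Its level in path2-1 was near the counting floor with an SD above the mean, so the size of its fold is uncertain. Of the 36 genes called in path1-4, 15 were higher and 21 lower, and 13 differed by more than 2-fold. The share that was higher, 41.7%, was 70.8% without control replicate 1, 52.2% and 55% without path1-4 replicates 1 and 3, and 71.4% with only the compared libraries. The list members called in path1-4 were HFR1 of the shade list (0.66 ± 0.13, edgeR adjusted p = 0.0475) and XTH9 of the cell wall list (-0.67 ± 0.11, edgeR adjusted p = 0.00915). HFR1 lost its call with only the compared genotypes (0.587), without the 2 doubles with path2-1 (0.111), without control replicate 2 (0.272) or 3 (0.140) and without path1-4 replicate 2 (0.196) or 3 (0.101), and XTH9 with only the compared genotypes (0.324) and without control replicate 2 (0.0616) or 3 (0.0513). Camera gave the jasmonate, leaf margin, rapid stress, immunity and shade lists adjusted p = 0.00897, 0.00153, 0.00129, 0.00153 and 0.0455 in path1-4 (adjusted p = 0.720, 0.550, 0.701, 0.793 and 0.626 with an estimated correlation). The other 3 genes called in path2-1, chosen for mention after their values were seen except LHY, were LHY (0.68 ± 0.11, edgeR adjusted p = 0.0251), AT3G18600 (0.56, edgeR adjusted p = 0.0452) and AT1G34844, which was lower (edgeR adjusted p = 0.000304) and is given no fold because its libraries in path2-1 were near the counting floor. In path2-1 the clock list held 1 called member and the photosynthesis list 0 of 33 (6 adjusted over the list alone, median -0.14), although camera gave photosynthesis an adjusted p = 3.47e-08 (adjusted p = 0.579 with an estimated correlation), leaf margin 0.00298 and flowering time 0.0343 (adjusted p = 0.550 for both with an estimated correlation). The LHY call ended with only the compared genotypes (0.209), without the 2 doubles with path2-1 (0.215) and without any 1 of control replicates 2 and 3 (0.120, 0.277) and path2-1 replicates 1, 2 and 3 (0.0635, 0.0578, 0.146). At an unadjusted edgeR p below 0.05 there were 2135 genes in path1-4 and 2832 in path2-1 of 20346 tested, and some genes fall there without any change. DESeq2 called 97 and 111. The path1-4 count was 113, 21 and 20 without control replicates 1, 2 and 3, 16 and 80 without path1-4 replicates 2 and 3, and 7 with only the compared libraries, and the path2-1 count was 42 and 2 without control replicates 1 and 3, 2 without path2-1 replicate 2 or 3, and 1 with only the compared libraries.

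The pat1-1path1-4 comparison asks what the joint mutation of PAT1 and PATH1 changed. Most heat genes and 13 of 25 immunity genes rose, and most drought and flavonoid genes fell. GRP9 was at 27.1 ± 5.27 CPM against 1.35 ± 0.581 in the control (4.32 ± 0.57, edgeR adjusted p = 1.66e-05), and PGAZAT was 343-fold higher (95% counting interval 94.5 to 2835). NUDT24, with 0 counts against 418, was at least 145-fold lower, taking 3 counts over the group as the floor. LAC2 (-2.52 ± 0.23, edgeR adjusted p = 2.69e-07), the isochorismate synthase ICS2 (-2.23 ± 0.25), AHP4 (-4.40) and DAA1 (-2.18) were lower. In all, 3215 genes were higher and 3141 lower, 1043 of them by more than 2-fold. Of the 25 immunity genes 13 rose, 0 fell and 12 were not called (15 adjusted over the list alone), with the receptor gene RLP23 at 1.52 and a camera adjusted p = 0.000130 (adjusted p = 0.720 with an estimated correlation). Of the 17 abscisic acid and drought genes 13 fell, 0 rose and 4 were not called (14 adjusted over the list alone), with HAI2 at -1.95 and RD26 at -0.73 and a camera adjusted p = 0.000333 (adjusted p = 0.626 with an estimated correlation). Of the 7 heat genes 6 rose and 1 was not called (6 adjusted over the list alone), with HSP70 at 1.71 and a camera adjusted p = 0.00129 (adjusted p = 0.550 with an estimated correlation). Of the 18 flavonoid genes 10 fell, 1 rose and 7 were not called (13 adjusted over the list alone), with a camera adjusted p = 0.00807 (adjusted p = 0.550 with an estimated correlation). Of the 33 photosynthesis genes 11 fell, 1 rose and 21 were not called (17 adjusted over the list alone), with a camera adjusted p = 0.0147 (adjusted p = 0.806 with an estimated correlation). Of the 14 shade genes 6 fell, 1 rose and 7 were not called (8 adjusted over the list alone), with a camera adjusted p = 0.0110 (adjusted p = 0.550 with an estimated correlation). Of the 21 decapping genes 8 rose, 2 fell and 11 were not called (10 adjusted over the list alone), with LSM3A at 1.13 and LSM1B at 0.78 and a camera adjusted p = 0.0356 (adjusted p = 0.550 with an estimated correlation). Of the 10 phosphate and iron genes 7 fell and 3 were not called (7 adjusted over the list alone), with a camera adjusted p = 0.0272 (adjusted p = 0.550 with an estimated correlation). Of the 18 glucosinolate genes 5 fell, with MYB28 at -0.76, and 13 were not called (5 adjusted over the list alone), with a camera adjusted p = 0.0426 (adjusted p = 0.793 with an estimated correlation). Of the 18 clock genes 7 rose, 3 fell and 8 were not called (10 adjusted over the list alone), with LHY at 1.40 (edgeR adjusted p = 5.69e-08) and RVE1 at 1.32 and a camera adjusted p = 0.160. FLC rose as well (1.44 ± 0.33).

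The pat1-1path2-1 comparison sets the joint mutation of PAT1 and PATH2 against the control. Its 3 libraries are among the 6 apart on the second principal component, so a batch cannot be told from the mutations in these values. Most shade genes fell and 4 of 7 heat genes rose, while most immunity and auxin genes were not called. Of the 12 cold genes 3 rose, 1 fell and 8 were not called (5 adjusted over the list alone, camera adjusted p = 0.486), and the 1 that fell, CBF2, lost its call in turn without each of the 6 compared libraries (0.0601 to 0.136) and with no filter (0.0598). The cold gene COR15A was at 478 ± 35.8 CPM against 186 ± 40.1 in the control (1.36, edgeR adjusted p = 0.000469). The transcription factor WRKY30 (2.54 ± 0.40, edgeR adjusted p = 6.94e-05), the methyltransferase IGMT2 (2.49 ± 0.31), GRP9 (2.36) and the receptor kinase CRK31 (2.29 ± 0.26) were among the largest increases. NUDT24 (-4.87 ± 0.93, edgeR adjusted p = 0.000612), AHP4 (-4.62), HIS1-3 (-3.10 ± 0.28, edgeR adjusted p = 1.08e-07) and MBP1 (-2.84) were among the largest decreases. In all, 3233 genes were higher and 3398 lower, 1208 of them by more than 2-fold. Of the 25 immunity genes 8 rose, 0 fell and 17 were not called (9 adjusted over the list alone), with EDS1 at 1.00 and a camera adjusted p = 0.000223 (adjusted p = 0.720 with an estimated correlation). Of the 30 auxin genes 12 fell, 2 rose and 16 were not called (15 adjusted over the list alone), with IAA29 at -0.81 and a camera adjusted p = 0.0148 (adjusted p = 0.720 with an estimated correlation). Of the 14 shade genes 8 fell, 1 rose and 5 were not called (11 adjusted over the list alone), with HB-2 at -0.66 and a camera adjusted p = 0.00807 (adjusted p = 0.550 with an estimated correlation). Of the 7 heat genes 4 rose, with HSP70 at 1.15, and 3 were not called (4 adjusted over the list alone), with a camera adjusted p = 0.00807 (adjusted p = 0.550 with an estimated correlation). Of the 21 decapping genes 8 rose, 1 fell and 12 were not called (11 adjusted over the list alone), with a camera adjusted p = 0.0166 (adjusted p = 0.550 with an estimated correlation). Of the 18 flavonoid genes 9 fell, 2 rose and 7 were not called (13 adjusted over the list alone), with TT4 at -1.10 and PAP1 at -1.85 and a camera adjusted p = 0.0426 (adjusted p = 0.626 with an estimated correlation). Of the 18 rapid stress genes 5 rose, 1 fell and 12 were not called (7 adjusted over the list alone), with a camera adjusted p = 0.0455 (adjusted p = 0.793 with an estimated correlation). The 1 that fell, RRTF1, lost its call without control replicate 3 (0.296) and without pat1-1path2-1 replicate 2 (0.0754) or 3 (0.0603). Of the 22 flowering time genes 8 fell, 4 rose and 10 were not called, with FD at -1.61 and AGL24 at -0.86 (camera adjusted p = 0.144).

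The path1-4path2-1 comparison sets the joint mutation of PATH1 and PATH2, with PAT1 not mutated, against the control. The other 3 of the 6 libraries apart on the second component belong to it, and the same limit holds. Most clock and cold genes were not called, and SQS2 fell. It was at 0.0968 ± 0.0838 CPM against 8.79 ± 0.995 in the control (-6.26 ± 0.60, edgeR adjusted p = 5.41e-07). SQS2 was near the counting floor in this genotype, so the size of its fold is uncertain. HFR1, which fell in pat1-1 and in the triple combination, rose to 109 ± 12.3 CPM (0.69 ± 0.13, edgeR adjusted p = 0.00110). The chloroplast-encoded NDHG (1.81) and NDHE (1.79), PRR3 of the clock (1.75 ± 0.22, edgeR adjusted p = 1.55e-05), HSD3 (1.66 ± 0.16) and WRKY30 (1.77 ± 0.40) were the largest increases among genes with a symbol that meet the naming rule. Chloroplast genes took 2.96% and 2.50% of the counts in replicates 2 and 3 of this genotype and 0.888 to 1.87% in the other 22 libraries. THI2.2 (-2.18 ± 0.32) and QQS (-1.99 ± 0.38) were among the largest decreases. In all, 1868 genes were higher and 2090 lower, 465 of them by more than 2-fold. Of the 18 clock genes 6 rose, 2 fell and 10 were not called (11 adjusted over the list alone), with LHY at 0.96 and CCA1 at 0.66 and a camera adjusted p = 0.0195 (adjusted p = 0.550 with an estimated correlation). Of the 12 cold genes 3 rose, 0 fell and 9 were not called (5 adjusted over the list alone), with COR15A at 1.24, KIN2 at 1.00 and COR15B at 0.85 and a camera adjusted p = 0.0491 (adjusted p = 0.768 with an estimated correlation). Of the 33 photosynthesis genes 4 fell, 1 rose and 28 were not called (5 adjusted over the list alone), with PSAF at -0.45 and a camera adjusted p = 0.00477 (adjusted p = 0.793 with an estimated correlation). AGL24 (-1.12, edgeR adjusted p = 1.18e-08), FD (-1.05), SEN1 (-0.95) and NAC6 (-1.15) fell. The number of called genes was 2448 without replicate 3 of this genotype.

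**Figure D4:**
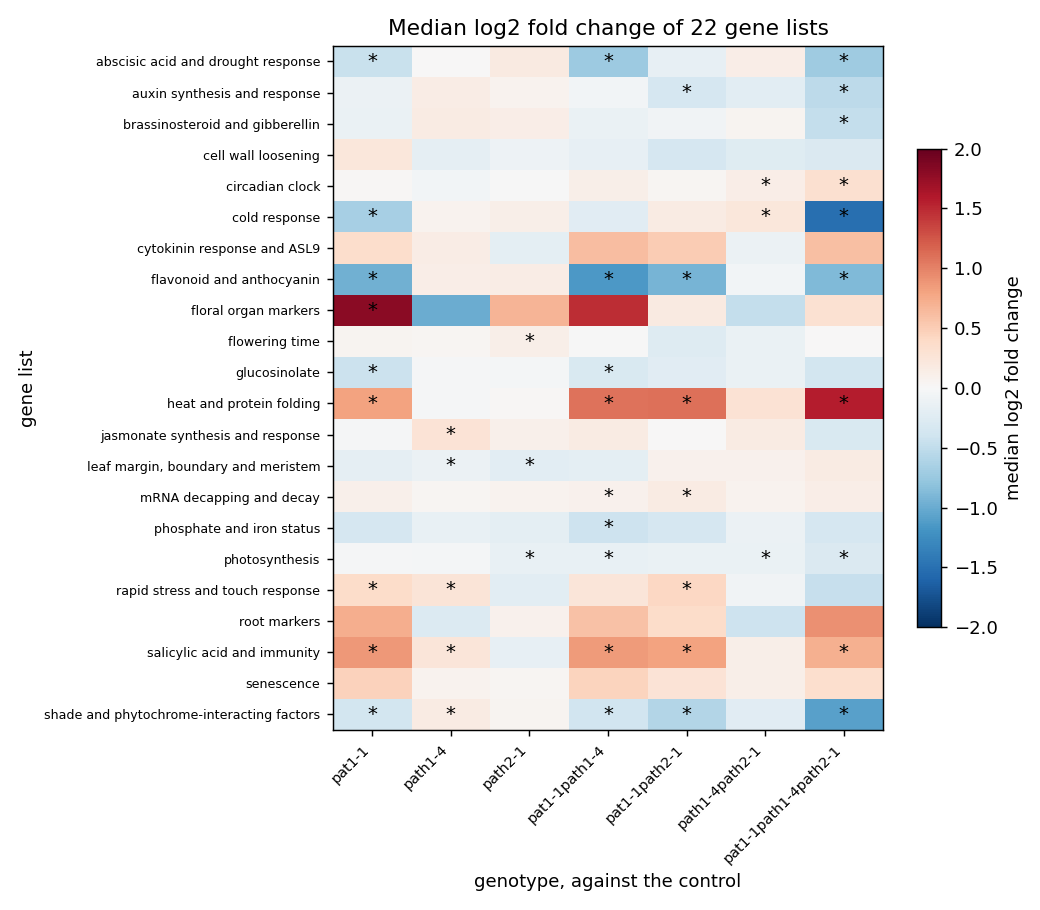
Median log2 fold change of each gene list in each genotype against the control, with an asterisk where the camera adjusted p was below 0.05 at the preset correlation. The shade list is at -1.09 in the triple combination and the heat list at 1.57, and none of the lists marked passes camera with an estimated correlation.

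Setting the triple combination against each double compares genotypes that differ by the remaining mutation. The 6 libraries of pat1-1path2-1 and path1-4path2-1 lie apart on the second principal component, and a batch there cannot be told from the mutation in the comparisons with these 2 doubles. The labels give no batch, so a batch of the triple libraries cannot be told from the mutation in any of these comparisons. Against pat1-1path1-4, of the 30 auxin genes 15 fell, 1 rose and 14 were not called (camera adjusted p = 1.85e-08, adjusted p = 0.196 with an estimated correlation), of the 14 shade genes 7 fell and 7 were not called (1.49e-06, 0.0953), and of the 16 brassinosteroid and gibberellin genes 8 fell and 8 were not called (1.96e-05, 0.0632). In that comparison 1654 genes were higher and 1772 lower, with PAP85 (1.92 ± 0.28) and MT1C (1.73) higher and TPS03 (-3.21) lower. Against pat1-1path2-1, 3675 genes were higher and 3600 lower, with FLC (4.25 ± 0.36, edgeR adjusted p = 2.46e-08), the invertase cwINV6 (2.78) and GRP9 (2.75) higher and RNS1 (-4.90), CIPK25 (-4.28) and AGL42 (-3.68 ± 0.31) lower. Of the 12 cold genes 8 fell, 0 rose and 4 were not called in that comparison (camera adjusted p = 9.34e-05, adjusted p = 0.435 with an estimated correlation). Against path1-4path2-1, 5038 genes were higher and 4954 lower, with GRP9 (3.97), GLYI4 (3.90) and the peroxidase Prx37 (3.76) higher and CIPK25 (-5.32), RNS1 (-4.97) and AHP4 (-4.95) lower. Of the 17 abscisic acid and drought genes 13 fell, 0 rose and 4 were not called in that comparison (camera adjusted p = 4.25e-05, adjusted p = 0.435 with an estimated correlation). RNS1 was near the counting floor in the triple combination, so the sizes of its folds against the doubles are uncertain.

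The pat1-1 mutation can be followed in 4 backgrounds, by setting each genotype with pat1-1 against the genotype that lacks only it. ASL9 was higher with pat1-1 in all 4, by 1.59 in the control background, 1.86 in path1-4, 1.51 in path2-1 and 2.03 in path1-4path2-1. GRP9, CML41, MT1C and GAD were higher and NUDT24, AHP4, DAA1, LAC2, HIS1-3 and TT4 lower in all 4 as well. The numbers of genes called for pat1-1 were 4653, 4487, 7853 and 9992 in these backgrounds, and 610 were called higher and 586 lower in all 4, against 12.2 and 12.1 for independent lists, a sum of 1196 that was 744 with only the compared genotypes. Between the 6 pairs of backgrounds, none of which shares a library, the pat1-1 fold changes correlated across genes at r = 0.676, 0.467, 0.530, 0.446, 0.630 and 0.206, a description without a p since genes are not independent replicates. Adding path1-4 called 36, 52, 4194 and 7275 genes in its 4 backgrounds, and adding path2-1 called 4, 4424, 3719 and 3426. The counts 7853, 9992, 4194, 7275, 4424 and 3719 each set libraries of the 6 that lie apart on the second component against others, so they and the correlations that use these libraries include any batch there. The fold changes of path1-4 had a median correlation of 0.065 between its backgrounds, 0.0041 with no filter, 0.0034 with DESeq2, 0.124 for genes with a mean log2 CPM of at least 3, and from 0.0194 without path1-4 replicate 1 to 0.0859 without pat1-1 replicate 1. Those of path2-1 had 0.0125, and from -0.0333 without path2-1 replicate 2 to 0.052 without path2-1 replicate 1. Between pat1-1 and path1-4 as single mutants, 22 genes were called in the same direction and 3 in opposite directions, against 4.08 for independent lists. These comparisons share the control libraries, so their lists are not independent. In 20 simulations of unchanged groups with shared controls a mean of 0.1 genes and at most 1 were shared. The simulated pat1-1 group had no changed genes, unlike the real list of 4653 calls, so a small overlap was set in advance. The simulations also fitted only the control and the singles. They therefore cannot show whether 22 exceeds what shared controls give. The fold changes of the 2 singles correlated at r = 0.413 (covariance 0.0758), against means of 0.480 and 0.0227 in these simulations. That overlap was 40 with DESeq2, 4 with only the compared genotypes, 90, 13 and 11 without control replicates 1, 2 and 3, and 11 and 51 without path1-4 replicates 2 and 3.

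The interaction contrasts ask whether effects of 2 mutations add up on the log2 scale. For pat1-1 with path1-4, 9 genes departed from the sum, 3 higher and 6 lower. Of the 20346 tested genes 1271 had an unadjusted edgeR p below 0.05, and some genes fall there without any change. In simulation this contrast recovered 20.9% of 1.5-fold departures, so 9 calls do not show that the effects add up. For pat1-1 with path2-1 there were 2999 genes, 1418 higher and 1581 lower, and for path1-4 with path2-1 there were 1674, 768 higher and 906 lower. The doubles in these last contrasts hold the 6 libraries that lie apart on the second principal component. FLC was at 2.22 ± 0.819 CPM in the control, 5.14 ± 2.36 in pat1-1, 2.60 ± 0.281 in path2-1 and 0.930 ± 0.491 in pat1-1path2-1, an interaction of -2.76 ± 0.52 (edgeR adjusted p = 0.00175). SQS2 was at 0.115 ± 0.136 CPM in path2-1 and at 3.33 ± 1.87 in pat1-1path2-1, an interaction of 5.80 ± 0.81 (edgeR adjusted p = 0.000138). The path2-1 level was near the counting floor, so the size of this interaction is uncertain. The triple combination departed from the sum of the 3 single effects at 1344 genes, 633 higher and 711 lower. RNS1 was at 2.81 ± 1.09 CPM in the control, 3.75 ± 3.02, 4.57 ± 1.24 and 4.79 ± 4.6 in the singles pat1-1, path1-4 and path2-1, and 0.134 ± 0.144 in the triple combination, a departure of -6.25 ± 1.36 (edgeR adjusted p = 0.00953). The triple level was near the counting floor, so the size of this departure is uncertain. The count for pat1-1 with path1-4 was 24 with DESeq2, 15 without control replicate 1, 5 without control replicate 2, 5 and 4 without pat1-1 replicates 2 and 3, and 5 without replicate 2 of path1-4 or of pat1-1path1-4. For path1-4 with path2-1 it was 568 with only the compared genotypes, 951 and 991 without control replicates 2 and 3, 943 without path1-4 replicate 2, 984 and 947 without path2-1 replicates 1 and 3, and 887 and 854 without path1-4path2-1 replicates 2 and 3. The pat1-1 by path2-1 count fell to 1963 without control replicate 2, 1867 without path2-1 replicate 3 and 1765 without pat1-1path2-1 replicate 1, and the 3-mutation count to 668 with only the compared genotypes and to 546 and 696 without control replicates 2 and 3.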

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

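The tests of a joint loss of PATH2 and a second paralog, of a batch covering libraries 16 to 21, of a split of on/off loci by 1 mutation and of a batch or pot of the pat1-1 single alone were chosen after the result was seen.

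The effect of a mutation differed between backgrounds by a test of the difference itself at 9 genes for pat1-1 with path1-4, 2999 for pat1-1 with path2-1, 1674 for path1-4 with path2-1 and 1344 for the triple combination against the sum of the singles. MED8, a subunit gene of the Mediator complex, had an interaction of 0.74 for pat1-1 with path1-4, with levels of 18.7 ± 1.52 CPM in the control and 29.7 ± 3.52 in pat1-1path1-4. Its edgeR adjusted p of 0.0189 rose to between 0.0534 and 0.0907 when any 1 of control replicates 2 and 3, pat1-1 replicates 2 and 3, path1-4 replicates 1 and 2 or pat1-1path1-4 replicate 1 was left out or the 2 doubles with path2-1 were left out, and to 0.219 with only the compared genotypes. For pat1-1 with path2-1 the interactions were 5.80 for SQS2, 2.86 for AT4, 2.28 for SPPL5, -2.83 for PDF1.3, -2.76 for FLC and -2.75 for cwINV6. The size for SQS2 is uncertain because its path2-1 level was near the counting floor. The PDF1.3 call ended without control replicate 2 (0.0571), pat1-1 replicate 2 (0.0619), path2-1 replicates 1 (0.0809) and 3 (0.0569) and pat1-1path2-1 replicate 1 (0.0704). For path1-4 with path2-1 they were 3.35 for KNAT1, 3.07 for scpl31, 2.56 for SPPL5, -3.00 for MAF5, -2.76 for CSLG2 and -2.05 for NATA1. The CSLG2 interaction was -1.45 without path1-4 replicate 3 (adjusted p = 0.171), and its call also ended with only the compared genotypes (0.108), without control replicates 2 (0.0695) and 3 (0.0735), path2-1 replicates 1 (0.0803) and 3 (0.0759) and path1-4path2-1 replicates 2 (0.0759) and 3 (0.0761). The NATA1 call ended without control replicates 2 (0.0588) and 3 (0.0514), path2-1 replicate 1 (0.0691) and path1-4path2-1 replicate 3 (0.0746). For the triple combination against the sum the departures were 4.33 for QQS, 4.2 for KNAT1, 4.17 for USPL1, -6.25 for RNS1, -5.90 for CSLG2 and -3.94 for NATA1. The size for RNS1 is uncertain because its triple level was near the counting floor. Without control replicate 2 the KNAT1 value was 3.57 (adjusted p = 0.105) and the USPL1 value 2.82 (adjusted p = 0.0721).

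Splits of the compared libraries into other groups were counted in fits of only those libraries. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 3089 genes in pat1-1 (highest other split 0), 7 in path1-4 (0), 1 in path2-1 (0), 4859 in pat1-1path1-4 (0), 6130 in pat1-1path2-1 (0), 2696 in path1-4path2-1 (1) and 7825 in the triple combination (1). It gave 2815 for the triple combination against pat1-1path1-4 (2), 7734 against pat1-1path2-1 (0) and 9471 against path1-4path2-1 (0), and in each of these 10 comparisons 1 of the 10 splits, the real one, gave as many. Every other split puts both genotypes into each group. A difference between the genotypes then widens the spread within groups and lowers the calls. The low counts of the other splits therefore do not decide whether the real count arises by chance. For the interactions 100 splits were drawn. As many genes as the real split were called in 2 of the 100 for pat1-1 with path1-4 (real 6, highest other 218), 1 for pat1-1 with path2-1 (real 2729, highest other 412), 2 for path1-4 with path2-1 (real 568, highest other 854) and 2 for the triple combination against the sum (real 668, highest other 3105). These splits mix genotypes with large effects of single mutations, so the share does not decide whether an interaction arises by chance. The other split with 218 genes for pat1-1 with path1-4, and the one with 3105 for the triple combination, called several times the real count, which points to a structure of the samples. The effects of the single mutations are part of any such structure, and its cause was not tested.

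The first pattern was a shift shared by the 2 doubles with path2-1: 1689 genes moved the same way when path2-1 was added to pat1-1 and to path1-4, 860 higher and 829 lower, against 406 for independent lists. GC content or gene length bias is argued against as the whole cause, since 67.9% of these genes stayed called in both after the trends were removed. Fold changes from the control followed exon length at rho = -0.183 in path1-4 and 0.170 in path1-4path2-1. The rho was -0.248 in pat1-1 and -0.0255 in pat1-1path2-1. It was higher with path2-1 in both cases, so a length trend may explain a part of the shift. Joint loss of PATH2 and a second paralog is argued against as the whole cause by the step from pat1-1path1-4 to the triple combination. There the median change of these genes was 0.0721 (quartiles -0.0825 to 0.251). It was 0.464 and 0.463 in the doubles, whose calls chose the genes, which raises those medians. In that step 62.5% kept the same sign, 311 were called in the same direction and 118 in the opposite one. Joint loss may therefore explain a part of the shift, although any batch of the triple libraries is part of that step too. A growth or library batch covering libraries 16 to 21 cannot be told apart from genotype, because the 6 libraries lie 28.3 units from the other 18 on the second principal component and the labels give no batch. Beside any such part, the shift may reflect such a batch, a pot size, or a state of these 2 genotypes that the triple combination lacks. Every count that sets these libraries against others carries the same doubt.

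A second pattern was a set of 4 loci that were on in some genotypes and off in others by at least 8-fold in every library. AT3G54823, a pseudogene (chromosome 3, 20305300 to 20309796), was on in 5 genotypes, AT1G64795 (chromosome 1, 24082579 to 24082848) in 6, AT3G01345 (chromosome 3, 129138 to 130749) in pat1-1 alone and AT4G05170 (chromosome 4, 2667798 to 2669441) in the 2 doubles with path2-1. A response to loss of 1 PAT gene in every background is argued against for these 4 loci only. Of them, 0% were split by the presence of 1 mutation across the 8 genotypes. A response that depends on the other mutations present would give no such split and stays open. Linkage to the mutated loci cannot be told apart from other causes with 4 loci, of which 0% lay within 5 Mb of PAT1, PATH1, PATH2 or SUMM2 against 32.1% of tested genes. Segregating differences between parent lines or inherited silencing may be behind them, and neither was tested.

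The last pattern was the 4653 calls in pat1-1 against 36 and 4 in the other singles. Fold changes in pat1-1 followed exon length at rho = -0.248 across genes, and 0.0312 after removal of the trends, but 73.7% of the calls stayed called in the same direction, which argues against GC content or gene length bias as the whole cause. The trend was not particular to pat1-1, since rho was -0.183 in path1-4, with its 36 calls, and -0.0394 in path2-1. The pat1-1 effect correlated at a median r = 0.499 across genes over the 6 pairs of backgrounds, which share no library. The pairs that hold the pat1-1 single gave r = 0.676, 0.467 and 0.530, which argues against a batch or pot of that single alone as the whole cause. The other pairs cannot bear on it. The median over all pairs was 0.235 with no filter and 0.297 with DESeq2, below the 0.3 that this test asked for. The genes called for pat1-1 in all 4 backgrounds numbered 1196, and 1036 and 1190 in those 2 settings. Between the control and path1-4 backgrounds 2671 genes were called for pat1-1 in the same direction and 4 in opposite directions. A pot size shared by all 4 genotypes with pat1-1 was not tested and stays open, because the labels do not give pot sizes by genotype. The biological explanation, that PAT1 has effects that PATH1 and PATH2 do not replace, may be right but stays a hypothesis. Few calls in path1-4 and path2-1 may also reflect little loss of function. Transcript levels do not decide this, with PATH1 at 78.0% of the control in path1-4 and PATH2 at 105% in path2-1. PAT1 was at 75.3% in pat1-1, which had 4653 calls. Adding path2-1 to pat1-1path1-4 called 3426 genes without libraries of the other 2 doubles, so path2-1 need not be without effect. On the third principal component, with 9.3% of the variance, the triple libraries lay from -33.2 to -26.4. Those of pat1-1path1-4 lay from 9.54 to 20.2. The labels give no batch, so a batch of the triple libraries cannot be told from path2-1 in that step. Protein levels of PATH1 and PATH2 in these singles would test for little loss of function.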

How the results depend on the processing

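The tests with trends of exon length and GC content removed, those leaving out the 2 doubles with path2-1, the agreement settings other than the log2 CPM minimum of 3 and the overlap settings were chosen after the result was seen. No paired analysis was possible because libraries are numbered 1 to 24 with no shared number. In fits of only the compared genotypes, which use fewer libraries, the counts were 3089 for pat1-1, 7 for path1-4, 1 for path2-1, 568 for path1-4 with path2-1 and 668 for the triple combination against the sum. DESeq2 called 97 genes in path1-4, 111 in path2-1 and 24 for pat1-1 with path1-4, and without the 2 doubles 2 genes were called in path2-1. The cause was not tested for the DESeq2 counts. The other settings that kept all libraries left each count within 1.5 times its value. Of the list tests 0 passed with an estimated correlation. The share of called genes that were higher moved from 41.7% to 71.4% in path1-4 with only the compared genotypes, and in path2-1 from 50% to 33.3% with RLE factors or no filter, 25.2% with DESeq2 and 0% with only the compared genotypes or without the doubles. For pat1-1 with path1-4 it moved from 33.3% to 50% with DESeq2. With 1 library left out it was up to 70.8% in path1-4, 0% to 64.3% in path2-1 and 13.3% to 50% for pat1-1 with path1-4. No setting moved the median of all genes by over 0.1, but the size factors center most genes in every setting, so this median could hardly move. A change in the total amount of mRNA would not show in these values. The numbers of higher and lower genes depend on the same scaling.

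Median agreement of the pat1-1 effect was 0.568 for genes with a mean log2 CPM of at least 3, 0.235 with no filter, 0.297 with DESeq2 and 0.536 with only the compared genotypes. For path1-4 it was 0.124, 0.0041, 0.0034 and 0.0832. The overlap of pat1-1 and path1-4 calls was 40 with DESeq2 and 4 with only the compared genotypes, and pat1-1 calls in all 4 backgrounds numbered 744 with only the compared genotypes. The cause was not tested for these.

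Leaving out each library in turn gave 2700 to 4454 genes in pat1-1, 16 to 113 in path1-4, 2 to 42 in path2-1, 4408 to 5979 in pat1-1path1-4, 5011 to 5932 in pat1-1path2-1, 2448 to 3345 in path1-4path2-1 and 7931 to 8797 in the triple combination. Against pat1-1path1-4, pat1-1path2-1 and path1-4path2-1 the triple combination had 2454 to 2633, 5796 to 6538 and 8605 to 9413. The interactions had 4 to 15 for pat1-1 with path1-4, 1765 to 3420 for pat1-1 with path2-1 and 854 to 2342 for path1-4 with path2-1, and the sum of singles 546 to 1691. Median agreement was 0.471 to 0.512 for pat1-1, 0.0194 to 0.0859 for path1-4 and -0.0333 to 0.052 for path2-1, the overlap 11 to 90 and pat1-1 calls in all 4 backgrounds 922 to 1187. Of 494 named gene results, 474 were called, and 362 kept direction and call in every setting with 0 reversed. Depth limits genes with 0 to 3 counts in a group, such as NUDT24, for which only a bound or an interval is given.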

Other observations

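Across the 4 backgrounds, genes outside the fixed lists also changed with pat1-1 each time, chosen for mention after their values were seen. PMZ was higher by 2.41, 2.08, 1.65 and 1.99 in the control, path1-4, path2-1 and path1-4path2-1 backgrounds, and PCR2, a membrane protein gene, by 2.01, 1.97, 1.74 and 2.19. The isochorismate synthase ICS2 was lower each time, at -1.63, -1.84, -1.60 and -2.91, and the microtubule-associated MDP40 at -1.61, -2.04, -1.94 and -3.37. The peptide gene CLE26 was at -1.42, -1.95, -1.37 and -2.04.

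The path2-1 effect in the pat1-1 and path1-4 backgrounds correlated at r = 0.475 across genes, with 1689 genes called in the same direction and 47 in opposite directions. The 6 libraries apart on the second principal component are the test groups in both, so a batch there gives the same sign. The path1-4 effect correlated at r = -0.257 between the path2-1 and pat1-1path2-1 backgrounds, with 329 genes called in the same direction and 1787 in opposite directions. In that pair the libraries apart on the second component are the test group once and the reference once, so a shift of them gives opposite signs. SQS2 was at 0.115 ± 0.136 CPM in path2-1, 0.0968 ± 0.0838 in path1-4path2-1, 0.757 ± 0.658 in the triple combination and 3.33 ± 1.87 in pat1-1path2-1, while genotypes without path2-1 were at 4.81 ± 0.512 to 8.79 ± 0.995.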
